A study of Ovis aries and Mus musculus with 10 samples.

How the data were processed

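Total RNA from mammary gland of sheep and of CD1 mice was measured on 10 Agilent miRNA arrays, with 1 array for each stage and day. The sheep arrays covered cycle day 15, gestation days 14, 64 and 125, and lactation day 60. The mouse arrays covered virgin animals, gestation days 10 and 17, and lactation days 2 and 10. Per the labels, tissue was snap-frozen, RNA was extracted with Trizol, samples had an RNA integrity number of 6 or more, and 100 ng of total RNA was labelled with Cy3 and hybridised. The arrays carried probes for 567 mouse miRNAs and 10 miRNAs of a mouse gammaherpesvirus, with 12493 spots per array, of which 11540 were for miRNAs, and a median of 20 spots per miRNA. The headers and names of the deposited scanner files placed mouse virgin and mouse gestation day 10 on slide 2 and the other 8 arrays on slide 1.

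The deposited scanner files hold intensity values in arbitrary units on a linear scale, and the processed signal among them is background-subtracted and detrended within each array, with no normalization between arrays, per the file headers. The file headers give Agilent Feature Extraction 10.5.1.1 on all 10 arrays, whereas the processing notes in the labels give version 9.5. The other columns used were flags of 0 or 1 for detection, signal well above background, saturation and outlier spots, set by the same software per the file headers. The value table the authors deposited is also an intensity on a linear scale with negative values. Checked against the scanner files, it equalled Agilent's total signal per miRNA multiplied by 1 constant per array, within 0.1% for 98.65 to 100% of the miRNAs with a total signal above 50. Its column medians were -0.603, 0.303, 0.26, -3.94 and -2.80 for the 5 sheep arrays in stage order, and -11.4, -5.23, 0.76, -2.35 and -11.6 for the 5 mouse arrays. The basis of these constants is not stated, so whether they scale or centre the arrays to a common value remained unknown.

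Analysis started from the processed signal of the scanner files. Spots that the software had marked as outliers were left out, spots were averaged for each probe, and probes were averaged to a value per miRNA. Each array was divided by the 75th percentile of the 94 miRNAs detected on all 10 arrays. The 5th percentile of the scaled values of detected miRNAs was taken on each array, and values below the highest of these, 0.029 or -5.11 on the log2 scale, were set to that floor. The floor rule was set after the scaled values had been looked at and before any model was fitted. The other main choices, the comparisons, the lists of miRNAs and most alternatives were made before the data were examined. miRNAs detected on at least 3 arrays were tested, which left 213, of which 28 lay at the floor on all 10 arrays. The number of arrays limits the precision. No spot was saturated, and 3 miRNAs had 1 probe.

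Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the miRNAs tested and a threshold of 0.05. An additive model with species and stage class (not pregnant, gestation, lactation) left 6 residual degrees of freedom and gave the comparisons of sheep with mouse and of the stage classes. Sheep in cycle and virgin mice formed the class not pregnant. A model with 6 means, 1 per species and stage class, left 4 residual degrees of freedom and tested whether the change from gestation to lactation differed between the species. No stage and day had a replicate, so the spread in these models came from different days of a stage class and from the species. No paired analysis was possible because the labels give no animal numbers shared between arrays. Steps between consecutive stages rest on 1 array on each side and were described without a test, as log2 differences with the error between spots, which covers spots within the arrays only. Changes in the 2 species were compared by Pearson and Spearman correlation across miRNAs, which are not independent replicates.

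Of 18 lists of miRNAs, 17 had at least 2 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists of a comparison. They were the miR-200 family, other epithelial miRNAs, the let-7 family, miR-17-92 and paralogous clusters, the miR-29 family, the miR-30 family, the miR-15/16 seed family, milk-abundant miRNAs, mammary-studied miRNAs, leukocyte and lymphoid miRNAs, erythroid miRNAs, endothelial miRNAs, striated muscle miRNAs, fibroblast and smooth muscle miRNAs, adipocyte-associated miRNAs, Dlk1-Dio3 cluster miRNAs and liver miRNAs. The list of neural miRNAs had 1 tested member and was not tested. The lists came from general knowledge and some share members. For a step, a list's median was placed among 10000 random lists matched on mean signal. The random members were drawn independently, so the percentile takes no account of list members that vary together.

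Named miRNAs were drawn from sets given by a fixed rule. Only some members of the larger sets are named, and the choice among them followed no stated rule. In each model comparison the set was up to 12 called miRNAs in each direction by size of change. Where under 5 were called, it also held the 5 with the lowest p. In each step the set was the 4 largest rises and falls among miRNAs detected on both arrays and above the median of the brighter array. miR-21, miR-205 and the miR-200 family were named in each model comparison, with the family given by its median in the steps, as were members of the lists as examples. Where all arrays of a group lacked signal well above background, a lower bound for the fold was computed. Each array of that group was given the lowest such signal on it, or the measured value or the floor if higher. The bounds compare plain group means and, unlike the changes beside them, are not adjusted for species.

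The alternatives tried were quantile normalization, the 75th percentile over all miRNAs, no scaling, normexp background correction with an offset of 50, Agilent's total signal, the brightest probe, the authors' value table, miRNAs detected on all 10 arrays, no filter, a floor 4 times lower, an intensity trend in eBayes, slide as a term, slide 1 alone, species alone, each species alone, only the 61 miRNAs whose names occur in the sheep annotation, and each array left out in turn. For lists, camera with an estimated correlation, fry and quantile normalization were tried. Chosen after seeing the data were the test without the 28 miRNAs at the floor on all arrays, which leaves 185 and was at first preferred over the planned set, and the test without mouse virgin and mouse gestation day 17. The planned set of 213 was kept as the main result. The 28 miRNAs have no variance and entered the prior of eBayes. Its prior variance was 0.00203 with them and 0.0764 without them, with 0.497 and 1.57 prior degrees of freedom. They therefore shaped the standard errors and p of all miRNAs in the main result.

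The comparison of lactation with gestation was tested on simulated data, with normal noise at the residual spread of each miRNA, in 20 simulations with 40 changed miRNAs each. It recovered 33% of 2-fold, 51% of 4-fold and 60% of 8-fold changes, all with the right sign, and 2.53% of its calls were false. Changed miRNAs were drawn from those with residual spread, and the noise held no difference shared by all miRNAs of an array. These shares therefore need not hold for the real arrays. Positions are those of the probe targets on mm9 as the files give them for 558 miRNAs. Gene annotation of mm9 and the sequences of sheep miRNAs were not used here, and the identity of the control spots named hur and mr is not stated in the files.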

Results

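Mammary gland miRNAs of sheep and mouse were measured on 10 arrays with mouse probes, from animals that were not pregnant through gestation to lactation. Of the 567 mouse miRNAs on the array, 267 were detected at least once and 94 on all 10 arrays. Sheep gland yielded 198 detected miRNAs in cycle, 206, 208 and 156 at gestation days 14, 64 and 125, and 156 in lactation. Mouse gland yielded 150 in virgin animals, 156 and 198 at gestation days 10 and 17, and 144 and 125 at lactation days 2 and 10. Before scaling, signal was lowest in lactation in both species. The 75th percentile of the 94 shared miRNAs was 1998 in sheep in cycle and 788 in lactation, and 598 in virgin mice and 246 at lactation day 10. All later values are relative to that percentile on each array, and differences are on the log2 scale.

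**Figure D1:**
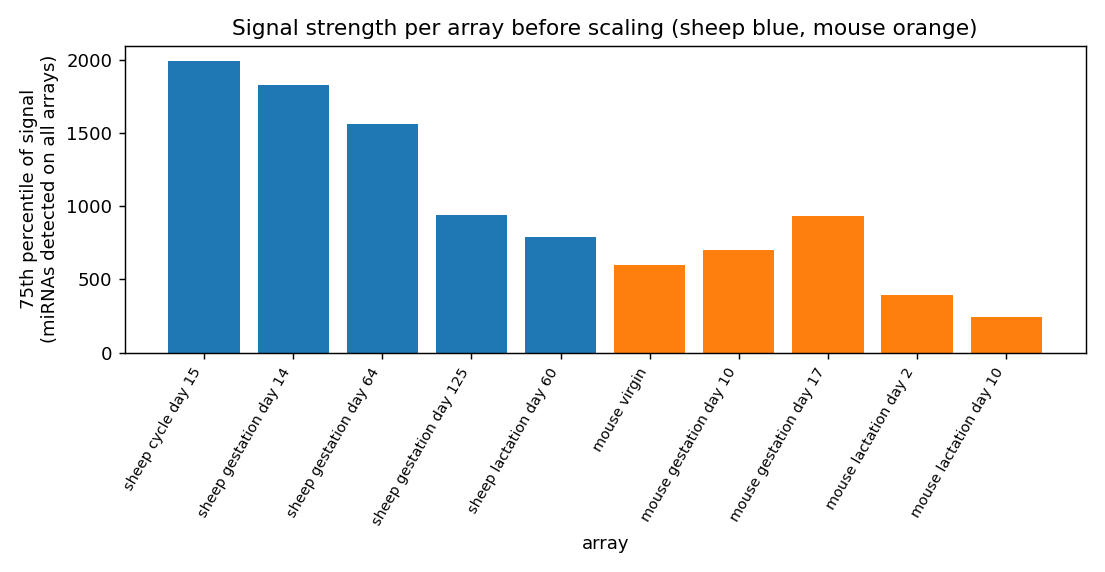
Bars give the 75th percentile of signal (arbitrary units, before scaling) over the 94 miRNAs detected on all arrays, with sheep in blue and mouse in orange. The values ran from 1998 in sheep in cycle to 246 in mouse lactation day 10.

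Species set the arrays apart more than stage did. The first principal component held 50.2% of the variance, with sheep between -10.4 and -5.76 and mouse between 6.49 and 10.4, and the next component held 24.3%. The median correlation across miRNAs between pairs of arrays was 0.925 within sheep, 0.916 within mouse and 0.798 between the species. No stage and day had a replicate array.

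miR-212 rose in lactation against gestation, with a log2 change of 1.53 ± 0.25 (standard error), from -4.46 ± 0.63 (SD, n = 5) to -2.69 ± 0.68 (SD, n = 3). Means with SD, here and below, are over the arrays of both species. The changes are adjusted for species, so the 2 need not match. miR-212 shares a cluster with miR-132, which lay at the floor on all 10 arrays, so a rise of the whole cluster was not seen. miR-212 itself lay at the floor on 3 arrays. miR-202-3p rose by 1.07 ± 0.20 and miR-103 by 1.01 ± 0.18, each on the log2 scale. miR-99a fell by 1.83 ± 0.33, from -0.08 ± 0.57 (SD, n = 5) to -2.14 ± 0.87 (SD, n = 3), miR-130a fell by 1.33 ± 0.24 and miR-361 fell by 0.99 ± 0.19. The probe targets of miR-212 and miR-99a lie on mouse chromosomes 11 and 16. These 6 miRNAs were the calls of limma among 213 tested (3 higher, 3 lower), each with an adjusted p of 0.0486. Within sheep and mouse alone the changes were 1.41 and 1.59 for miR-212, 0.61 and 1.41 for miR-202-3p, 1.02 and 1.03 for miR-103, -1.42 and -2.09 for miR-99a, -1.17 and -1.40 for miR-130a, and -0.80 and -1.12 for miR-361. Without scaling all miRNAs shifted by a median of -0.66, the calls became 1 higher and 21 lower, and miR-103 turned to -0.09. With normexp the median shift was 0.65, the calls were 5 higher and 2 lower, and miR-361 turned to 0.01.

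These 6 calls depended on single arrays and on settings. Without sheep gestation replicate 1 (day 125) there were 5, without mouse lactation replicate 2 (day 2) there was 1, and without any other single array there was none by limma, with 24 to 40 miRNAs at an unadjusted p under 0.05. Quantile normalization left 1 call, with 1 higher and 0 lower. The 75th percentile over all miRNAs, the authors' value table, the brightest probe, no filter, slide as a term, slide 1 alone and mouse alone each left 0 by limma, with 29, 13, 40, 32, 28, 26 and 19 at an unadjusted p under 0.05, against 34 in the main result. Leaving out the 28 miRNAs at the floor on all arrays, a choice made after the counts were seen, gave 15 calls (7 higher, 8 lower), and a floor 4 times lower gave 24.

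miR-146b, a brake on innate immune signalling, and miR-375, first found in pancreatic islets, had the largest differences between lactation and gestation without reaching the threshold. miR-146b was higher by 3.40 ± 0.67 and miR-375 by 3.20 ± 0.62, each with an adjusted p of 0.0502, and miR-375 lay at the floor on all 5 gestation arrays. miR-148a, abundant in milk, was higher by 2.63 ± 0.78 (adjusted p = 0.136). miR-21 was lower at -0.79 ± 0.30 (adjusted p = 0.243) and miR-205 at -1.05 ± 0.60 (adjusted p = 0.473).

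**Figure D2:**
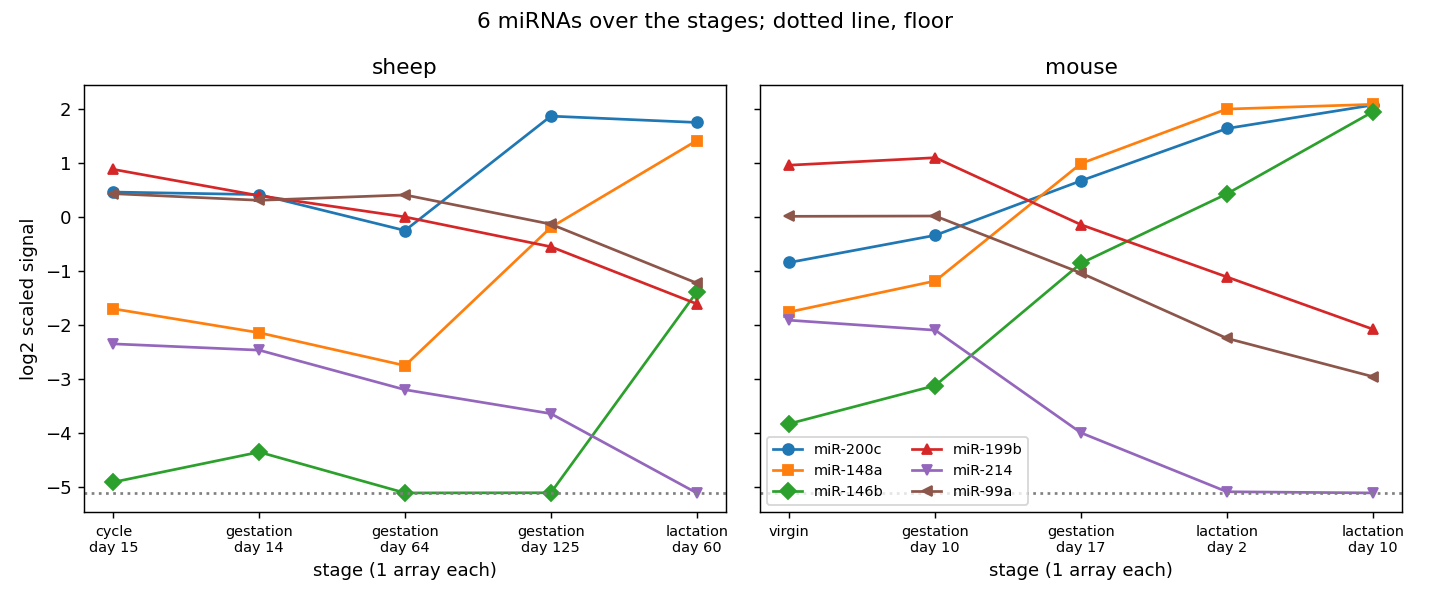
Log2 scaled signal of miR-200c, miR-148a, miR-146b, miR-199b, miR-214 and miR-99a over the stages of sheep and mouse, with the floor of -5.11 as a dotted line. The 6 miRNAs were chosen after their values were seen, and miR-146b in mouse ran from -3.83 in virgin animals to 1.95 at lactation day 10.

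**Figure D3:**
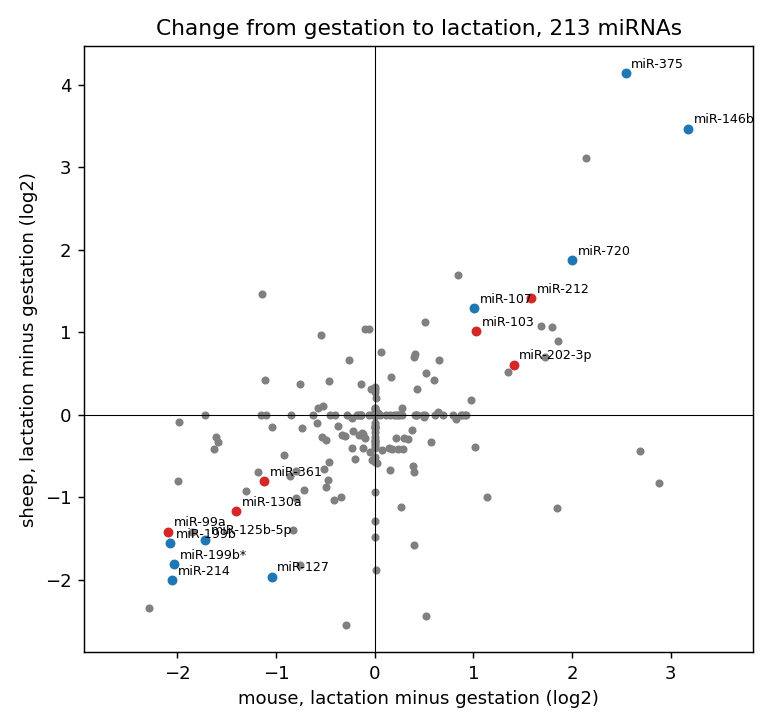
Log2 change from gestation to lactation in mouse against sheep for 213 miRNAs, with the 15 called without the 28 miRNAs at the floor labelled and 6 of them, also called with all 213, in red. miR-212 lay at 1.41 in sheep and 1.59 in mouse, and miR-99a at -1.42 and -2.09.

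The miR-200 family, which represses ZEB1 and ZEB2 and marks epithelium, was higher in lactation than over the gestation days together, and the fibroblast and smooth muscle list was lower. For the miR-200 family in sheep this held against days 14 and 64 only, as the list mean was -0.73, -1.47 and 0.75 at gestation days 14, 64 and 125 and 0.40 in lactation. miR-200a, miR-200b, miR-200c, miR-141 and miR-429 were higher by 1.54 ± 0.72, 1.59 ± 0.66, 1.48 ± 0.55, 1.36 ± 0.58 and 0.62 ± 0.74 on the log2 scale. miR-199a-5p was lower at -2.30 ± 0.63, miR-214 at -2.06 ± 0.47 (at least 2.48-fold) and miR-199b at -1.84 ± 0.40, while miR-145 was lower at -0.58 and miR-143 at -0.13. With camera at the preset correlation the miR-200 median of 1.48 had an adjusted p of 0.0251, against an adjusted p = 0.545 with an estimated correlation. No member was called over all miRNAs tested or adjusted over the list alone, and adjusted p was 0.185 with fry and 0.0577 with quantile normalization. The fibroblast median of -1.84 had an adjusted p of 0.0251, against an adjusted p = 0.543 with an estimated correlation, with 0 members called over all miRNAs tested and 3 lower adjusted over the list alone, and adjusted p was 0.111 with fry and 0.0577 with quantile normalization. Without scaling, where all miRNAs shifted by a median of -0.665, the miR-200 median was 0.39 and the fibroblast median -2.93. With normexp, where they shifted by 0.648, the fibroblast median was -0.36. Relative to these shifts, the direction of both lists stayed the same.

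Other groups did not pass this test between lactation and gestation. Milk-abundant miRNAs had a median of 0.46 (adjusted p = 0.0635), with 3 higher adjusted over the list alone. Adipocyte-associated miRNAs had a median of 0.18 (adjusted p = 0.123), with miR-103 called over all and 2 members adjusted over the list alone. miR-17-92 and paralogous clusters had a median of -0.25 (adjusted p = 0.23) and the miR-15/16 seed family one of -0.22 (adjusted p = 0.23). The leukocyte and lymphoid median was -0.36, the erythroid one 0.41 and the Dlk1-Dio3 one -0.06 (adjusted p = 0.275 each). Medians were 0.43 for other epithelial miRNAs, 0.14 for the let-7 family, 0.35 for the miR-29 family, 0.15 for the miR-30 family, -1.01 for striated muscle and 0.27 for liver miRNAs (adjusted p = 0.399 each). Mammary-studied miRNAs had a median of -0.14 (adjusted p = 0.634), with miR-212 called, and endothelial miRNAs one of 0.05 (adjusted p = 0.775). Of the neural miRNAs only miR-128 was tested, at -0.14. Relative to the shift of all miRNAs, the medians of the let-7, miR-29, miR-30 and adipocyte lists turned below 0, and that of Dlk1-Dio3 above 0, both without scaling and with normexp. Those of other epithelial miRNAs and the miR-30 family turned below 0 with slide as a term, and that of endothelial miRNAs with quantile normalization and normexp.

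miR-146b rose from animals not pregnant to lactation by 4.30 ± 0.83 on the log2 scale, from -4.37 ± 0.77 (SD, n = 2) to 0.33 ± 1.67 (SD, n = 3), and miR-212 rose by 1.90 ± 0.31. miR-214 and miR-199b changed by -2.99 ± 0.58 (at least 4.78-fold lower) and -2.57 ± 0.49. miR-99a fell by 2.23 ± 0.41 and miR-130a fell by 1.55 ± 0.30. miR-410 and miR-218 were called too, lower at -0.47 ± 0.04 and -0.07 ± 0.01, but lay at the floor on 7 and 8 of the 10 arrays, and neither was among the 11 calls without the 28 miRNAs at the floor on all arrays. These were the 8 calls of limma (2 higher, 6 lower), with an adjusted p of 0.00359 for miR-410 and 0.0434 for each of the others. miR-375 was higher by 3.15 ± 0.76 (at least 6.74-fold, adjusted p = 0.0691) and miR-148a by 3.40 ± 0.96 (adjusted p = 0.112). miR-127 was lower at -2.09 ± 0.44 (at least 2.9-fold, adjusted p = 0.0528) and miR-379 at -2.09 ± 0.48 (at least 2.91-fold, adjusted p = 0.067). miR-21 was lower at -0.95 ± 0.37 and miR-205 at -0.27 ± 0.74.

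Single arrays and settings also moved the 8 calls between lactation and animals not pregnant. Leaving out sheep gestation replicate 2 (day 14), sheep gestation replicate 3 (day 64), sheep lactation replicate 1 or mouse lactation replicate 1 (day 10) left 1, and leaving out mouse lactation replicate 2 (day 2) left 2. Leaving out mouse gestation replicate 2 (day 17) left 3, and leaving out mouse virgin replicate 1 or mouse gestation replicate 1 (day 10) left 4. Limma called 0 with quantile normalization, the brightest probe or the authors' value table, with 38, 41 and 31 at an unadjusted p under 0.05, against 40 in the main result. No scaling shifted all miRNAs by a median of -0.78 with 0 higher and 9 lower, and normexp gave 8 higher and 6 lower. The authors' value table shifted them by -0.20. A floor 4 times lower gave 29, and slide as a term 1.

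miR-141 was 2.38 ± 0.71 higher in lactation than in animals not pregnant, miR-200a 2.27 ± 0.88, miR-200b 2.10 ± 0.81, miR-200c 2.10 ± 0.68 and miR-429 0.89 ± 0.90. In the same order, the changes were 1.28, 0.98, 0.72, 1.29 and 0.08 within sheep. Within mouse they were 3.18, 3.24, 3.18, 2.70 and 1.65. The miR-200 family median of 2.10 had an adjusted p of 0.0105, against an adjusted p = 0.528 with an estimated correlation, with 0 members called over all and 4 adjusted over the list alone, and it was 0.92 without scaling, 1.31 with slide as a term and 1.09 on slide 1 alone, and fry gave an adjusted p of 0.129. Milk-abundant miRNAs had a median of 0.89 with an adjusted p of 0.0231, against an adjusted p = 0.197 with an estimated correlation, with 1 called over all and 3 adjusted over the list alone, and it was 0.12 without scaling, 0.44 with the authors' values and 0.59 with normexp, and quantile normalization gave an adjusted p of 0.0657. miRNAs of the imprinted Dlk1-Dio3 cluster had a median of -0.33 with an adjusted p of 0.00277, against an adjusted p = 0.197 with an estimated correlation, with 1 called over all and 3 lower adjusted over the list alone, and it was -1.09 without scaling and -0.20 with normexp. Of the 14 members tested, 3 lay at the floor on all arrays and 8 more on 7 to 9 arrays, so this test rests mostly on members with hardly any signal. The list medians without scaling are to be read against the shift of all miRNAs there, a median of -0.784. The fibroblast median was -2.55 (adjusted p = 0.105). Striated muscle miRNAs had a median of -2.4 with an adjusted p of 0.0801 by camera. That value rests on the array of virgin mice, where the list mean was -1.33 against -5.11 in sheep in cycle.

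miR-410, of the Dlk1-Dio3 cluster, was the only miRNA called between gestation and animals not pregnant, lower at -0.45 ± 0.04 (adjusted p = 0.00239). It lay at the floor on 7 of 10 arrays, so the call rests on values of -4.74 in sheep in cycle and -4.56 in virgin mice, close to the floor of -5.11. miR-223, a granulocyte miRNA, was lower at -1.34 ± 0.46, miR-551b at -0.32 and miR-374 at -0.24 (adjusted p = 1 each), and miR-218 at -0.07 (adjusted p = 0.0812). miR-141 was higher by 1.02, miR-205 by 0.77, miR-200a by 0.73, miR-200c by 0.61, miR-200b by 0.50 and miR-429 by 0.27, and miR-21 was lower at -0.16 (adjusted p = 1 each). Limma found 5 miRNAs at an unadjusted p under 0.05. Leaving out sheep cycle replicate 1 gave 7 calls and leaving out mouse virgin replicate 1 gave 5. Slide 1 alone gave 6, sheep alone 6 and mouse alone 5. Limma called 0 with quantile normalization, no scaling, normexp, the brightest probe and the authors' value table, with 5, 2, 53, 7 and 10 at an unadjusted p under 0.05. Without the 28 miRNAs at the floor it called 0, with 4 at an unadjusted p under 0.05. Normexp shifted all miRNAs by a median of -0.65 and the authors' value table by -0.41.

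Erythroid and striated muscle miRNAs were lower in gestation than in animals not pregnant in mouse, and no test compared this with sheep. In sheep, miR-451 was higher by 0.36 and miR-133b by 0.33 from the floor. The other members lay at the floor in sheep, where a fall could not be seen. The difference thus rests on the single array of virgin mice, where the muscle list mean was -1.33 against -5.11 at mouse gestation day 10. The values that follow are from the model over both species. Of the red cell miRNAs, miR-486 was lower at -1.07 ± 0.48, miR-144 at -0.88 ± 0.42 and miR-451 at -0.66 ± 0.55. Of the muscle miRNAs, miR-133a was lower at -1.46 ± 0.92, miR-1 at -1.32 ± 1.11, miR-133b at -1.31 ± 1.13 and miR-206 at -0.93 ± 0.41. The erythroid median of -0.88 had an adjusted p of 0.0262, against an adjusted p = 0.658 with an estimated correlation, and was -0.06 on slide 1 alone, -1.48 with the authors' values and -1.34 with normexp, and fry gave an adjusted p of 0.636. The striated muscle median of -1.31 had an adjusted p of 0.0262, against an adjusted p = 0.67 with an estimated correlation, and moved to 0.34 on slide 1 alone and to -2.09 with the authors' values. Fry gave an adjusted p of 0.709 for it, and neither list had a member called over all or adjusted over the list alone. The Dlk1-Dio3 median of -0.26 had an adjusted p of 1e-05, against an adjusted p = 0.0758 with an estimated correlation, with 1 called either way, and was -0.58 without scaling and -0.97 with normexp, but 11 of the 14 members lay at the floor on 7 or more arrays. The miR-200 family median was 0.61 (adjusted p = 0.129 by camera) and turned to -0.32 with the authors' value table, where all miRNAs shifted by -0.41. Normexp shifted all miRNAs by -0.65 in this comparison.

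miR-331-3p was higher in sheep than in mouse by 2.66 ± 0.18 on the log2 scale (adjusted p = 0.000145), and miR-195 was lower at -5.16 ± 0.31 (adjusted p = 0.000107). miR-204 was higher in sheep by 2.13 ± 0.51, miR-361 by 2.01 ± 0.16, miR-423-5p by 1.86 ± 0.15 (at least 2.27-fold) and the leukocyte miR-142-3p by 1.51 ± 0.41. miR-322 was lower at -4.57 ± 0.34, miR-709 at -4.13 ± 0.51, miR-16 at -4.00 ± 0.21 (at least 15.7-fold, adjusted p = 6.22e-05), the red cell miR-451 at -3.40 ± 0.43, miR-193b at -2.70 ± 0.43, miR-223 at -2.59 ± 0.36, miR-378 at -2.41 ± 0.44 and miR-429 at -2.35 ± 0.64. miR-16 lay at the floor on all 5 sheep arrays, miR-322 on 4, and miR-195, miR-709 and miR-223 on 3 each, so the size of these differences depends on the floor. Within the let-7 family, let-7a was higher by 0.93 ± 0.22 and let-7b by 0.55 ± 0.13, whereas let-7c was lower at -1.91 ± 0.15, let-7d at -1.84 ± 0.29 and let-7i at -0.71 ± 0.16. miR-21 was higher by 0.67 ± 0.26 (adjusted p = 0.124), miR-205 by 0.68, miR-200a by 0.74, miR-200b by 0.55, miR-200c by 0.51 and miR-141 by 0.84. Limma called 46 miRNAs between sheep and mouse (18 higher, 28 lower). The probes were made for mouse, and how well each matches the sheep miRNA was not examined here.

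The balance of higher and lower miRNAs between the species moved with scaling. It was 69 higher and 18 lower without scaling, which shifted all miRNAs by a median of 0.69, and 9 higher and 51 lower with normexp, which shifted them by -0.46. The 75th percentile over all miRNAs gave 23 and 23, quantile normalization 24 and 23, and with the authors' values there were 3 higher and 11 lower. Among the 61 miRNAs with a name in the sheep annotation, 13 were called, with 7 higher and 6 lower. A floor 4 times lower gave 95. The miR-15/16 family median of -1.11 had an adjusted p of 0.0467, against an adjusted p = 0.315 with an estimated correlation, with 3 lower both over all and adjusted over the list alone, and was -0.58 without scaling. The adipocyte-associated median of -1.20 had an adjusted p of 0.0467, against an adjusted p = 0.315 with an estimated correlation, with 4 lower both ways, and was -0.06 without scaling, and quantile normalization gave an adjusted p of 0.0552. Milk-abundant miRNAs had a median of 0.39 and a mean of -0.09, with the test pointing up, and leukocyte and lymphoid miRNAs a median of 0.13 and a mean of -0.20, with the test pointing down.

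miR-200b* and miR-146a were called for a different change from gestation to lactation in sheep than in mouse, each by 0.28, with standard errors of 0.01 and 0.02. miR-200b* lay at the floor on 9 arrays and miR-146a on 8, so each call came from 1 or 2 arrays just above the floor. The standard error of miR-200b* equalled that of miRNAs at the floor on all arrays, so it measures no spread between arrays. miR-204 differed most in size among the values next in rank, by 2.61 ± 0.45 (adjusted p = 0.136), followed by miR-362-3p at -0.42 and miR-33 at 0.08 with the same adjusted p. miR-21 differed by 0.12, miR-205 by 0.38, miR-200a by -0.96, miR-200b by -0.73, miR-200c by -0.62, miR-141 by -1.02 and miR-429 by 0.30 (adjusted p = 1 each). Adjusted p was 0.00379 for miR-200b* and 0.0199 for miR-146a, and 16 miRNAs had an unadjusted p under 0.05. Limma called 0 without the 28 miRNAs at the floor, with 17 at an unadjusted p under 0.05, and 0 with normexp, with 9, where miR-200b* turned to -0.23. Quantile normalization gave 8 higher and 1 lower, the 75th percentile over all miRNAs 5 and 0, and with the authors' values there were 3 higher and 1 lower. The median shift was -0.36 with normexp and 0.25 with the 75th percentile over all miRNAs. Leaving out mouse lactation replicate 2 (day 2) gave 19, mouse lactation replicate 1 (day 10) 10, mouse gestation replicate 2 (day 17) 8 and mouse gestation replicate 1 (day 10) 5, and without sheep gestation replicate 2 (day 14) there was 0 by limma, with 11 at an unadjusted p under 0.05. No list was called. The test pointed up for the miR-29, milk-abundant, leukocyte and fibroblast lists, with medians of -0.53, -0.03, -0.26 and -0.06.

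The correlation between the species was higher for the change from gestation to lactation than for the change into gestation, and this difference was not tested. Across miRNAs, the sheep and mouse changes correlated with r = 0.54 (Spearman 0.379) from gestation to lactation, with 79 of 116 miRNAs of the same sign. From animals not pregnant to lactation r was 0.434 (Spearman 0.312), with 71 of 108. From animals not pregnant to gestation r was -0.109 (Spearman -0.0136), with 57 of 115, and it turned to 0.247 with normexp and 0.124 with the authors' value table. The class not pregnant rests on 1 array in each species, as does lactation in sheep. Signal before scaling was lower in lactation than in gestation in both species, with folds of 0.546 in sheep and 0.39 in mouse. Whether this shared fall added to the correlation was not tested.

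In sheep the step to gestation day 125 held more differences than those to days 14 and 64 except with normexp, where the step to day 14 held more, and 55 of 145 miRNAs detected on both arrays differed at least 2-fold (29 higher, 26 lower). miR-429 was higher by 3.01, miR-30a by 2.74, miR-148a by 2.56, miR-200a by 2.34, miR-200b by 2.17, miR-200c by 2.12 and miR-141 by 1.48. miR-125a-3p was lower at -5.30, miR-494 at -4.09, miR-1224 at -3.87, miR-801 at -3.14 to the floor, and miR-205 at -2.30. From cycle to day 14, 10 of 189 differed so (5 higher, 5 lower), with miR-494 higher by 2.99 and miR-1224 by 2.49, and miR-223 lower at -2.31 to the floor. From day 14 to day 64 it was 17 of 190 (13 higher, 4 lower), with miR-801 higher by 2.00 and miR-205 by 1.02, and miR-429 lower at -1.33 and miR-127 at -1.24. From day 125 to lactation it was 30 of 139 (7 higher, 23 lower), with miR-146b higher by 3.72 from near the floor, miR-29c by 2.29, miR-29b by 2.01 and miR-204 by 1.90, and miR-127 lower at -2.35 and miR-379 at -2.19. Between cycle and lactation 38 of 152 differed so (15 higher, 23 lower), with miR-375 higher by 4.14 from the floor, miR-148a by 3.12 and miR-451 by 2.06, and miR-96 lower at -2.98 and miR-214 at -2.76, each to the floor, and miR-199a-5p at -2.69. The miR-200 family median was 2.17 in the step to day 125, at percentile 99.8 of matched random lists, and the fibroblast median was -1.14 there, at percentile 2.35, but above 0 with the authors' values, which move all miRNAs of an array alike. In the other steps the miR-200 median was -0.21 to day 14 (percentile 32.1) and -0.72 to day 64 (percentile 0), where all 5 members were lower. From day 125 to lactation it was -0.22, and all 5 members were lower there too. In that step the median lay above 0 with the 75th percentile over all miRNAs, which moves all miRNAs of an array alike. miR-21 differed by 0.62, -0.66, 0.15 and -0.55 over the consecutive steps and by -0.45 between cycle and lactation, and miR-205 by -0.01 to day 14, 0.27 from day 125 to lactation and -1.02 between cycle and lactation. These steps rest on 1 array on each side and have no test. From cycle to day 125 the control features hur_4 and hur_6 moved against miR-494 and miR-1224, so a difference between arrays was not set apart from stage.

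In mouse, miR-146b was higher at lactation day 10 than in virgin animals by 5.78, miR-181a by 4.43 and miR-181b by 4.23, each of these 2 from the floor, and miR-96 by 3.96. miR-200a was higher by 3.85, miR-200b by 3.55, miR-141 by 3.17 and miR-200c by 2.92, and miR-199b* was lower at -3.20, miR-199a-5p at -3.13, miR-199b at -3.04 and miR-99a at -2.97. In this comparison 39 of 107 miRNAs differed at least 2-fold (24 higher, 15 lower). From virgin to gestation day 10 it was 11 of 142 (6 higher, 5 lower), with miR-196a higher by 1.55 and miR-205 by 1.34, and miR-133b lower at -4.61, miR-486 at -2.26 and miR-144 at -2.25, each to the floor. From day 10 to day 17 it was 29 of 149 (16 higher, 13 lower), with miR-133b higher by 3.18 from the floor, miR-146b by 2.26 and miR-148a by 2.18, and miR-801 lower at -3.24 and miR-214 at -1.90. From day 17 to lactation day 2 it was 19 of 143 (8 higher, 11 lower), with miR-181b higher by 1.52 and miR-146b by 1.29, and miR-205 lower at -1.5, miR-204 at -1.33 and miR-199a-5p at -1.25. From lactation day 2 to day 10 it was 14 of 120 (9 higher, 5 lower), with miR-375 higher by 2.55, miR-146b by 1.52 and miR-200a by 1.23, and miR-93 lower at -1.51 and miR-19a at -1.12. The miR-200 family median was above 0 in each mouse step, at 0.72, 1.08, 0.86 and 0.43, but lay below 0 for both lactation steps without scaling and for both gestation steps with the authors' values, which multiply all miRNAs of an array by 1 factor. The 75th percentile of signal before scaling had ratios of 0.421 and 0.623 in those lactation steps. miR-21 differed by -0.13, -0.86, -0.10 and -0.53 over the consecutive steps and by -1.63 over the whole course, and miR-205 by 0.78 to day 17, -0.38 from lactation day 2 to day 10 and 0.24 over the whole course. Virgin animals and gestation day 10 were on another slide than the later mouse arrays, so the step to day 17 and the whole course cross slides.

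**Figure D4:**
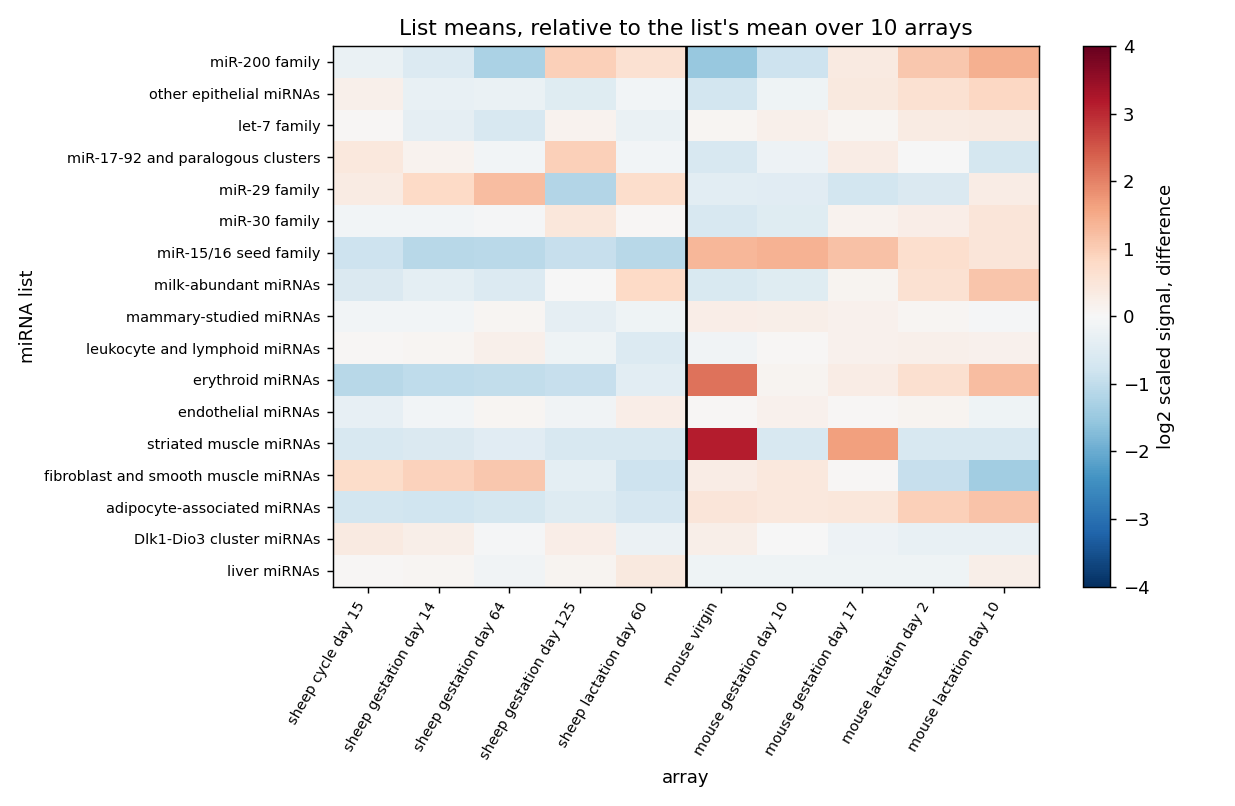
Heat map of the mean log2 scaled signal of 17 lists on 10 arrays, each relative to its mean over the arrays. Striated muscle miRNAs stood at -1.33 in virgin mice and -2.85 at mouse gestation day 17, and at -4.92 or lower on the other arrays.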

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

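Of the tests in this part, the conditions for the regrouping of arrays were written after the counts were seen. Between sheep and mouse, limma called 46 miRNAs, and 1 of 100 divisions of the 10 arrays into groups of 5, the real one, gave as many, with 6 the highest among the others. Between lactation and gestation it called 6, and 1 of 56 divisions of the 8 arrays into 3 and 5, the real one, gave as many. The highest other count there was 5, with sheep gestation days 14 and 64 and sheep lactation as the group of 3. A group of the 3 mouse arrays on slide 1 gave 4. Among the 24 divisions that keep 1 sheep and 2 mouse arrays in the group of 3, the real one alone gave as many, with 1 the highest among the others, and 24 divisions cannot give a share far under 0.05. The real division thus gave the most calls for both counts, which does not exclude chance. Every other division of the 10 arrays puts sheep and mouse arrays together in each group, so low counts there could be foreseen. Between lactation and gestation the next division gave 5 against 6, and the 6 calls share an adjusted p of 0.0486 by limma. Without sheep gestation replicate 1 (day 125) there were 5 calls, without mouse lactation replicate 2 (day 2) 1, and without any other single array 0 by limma, with 24 to 40 miRNAs at an unadjusted p under 0.05.

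The miR-30 family stood apart at sheep gestation day 125, with a list mean of -0.90 against -1.32 on the next sheep array, and a gap of 0.747 of the whole range. Erythroid miRNAs stood apart in sheep lactation, at -3.64 against -4.16 on the next array, with a gap of 0.759, which rests on miR-451 alone, as miR-144 and miR-486 lay at the floor on all sheep arrays. Liver miRNAs stood apart at mouse lactation day 10, at -4.70 against the floor of -5.11 on the other mouse arrays, which makes the gap 1 by construction. These were 3 of 40 groups of values examined, where chance alone gives about 1 in 20.

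miR-146a and miR-200b* changed differently from gestation to lactation in sheep and mouse, by 0.278 and 0.279 on the log2 scale. Both lay at the floor on most arrays, and neither difference exceeded 1.21-fold. The viral miRNA mghv-miR-M1-2 was detected on all 10 arrays, with a signal between 20.2 and 50.5, whereas the other 9 viral miRNAs were detected on none. Its source was not analysed here.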

How the results depend on the processing

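Left out after the data were seen were the 28 miRNAs at the floor on all arrays, and mouse virgin with mouse gestation day 17. The other alternatives were planned. The cause of a change in a count was not tested unless stated. Counts are calls of limma, given in turn for the comparisons they moved by more than 1.5 times.

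Sheep against mouse had 46 calls. There were 87 without scaling, 14 with the authors' values, 95 with a floor 4 times lower, 13 among names in the sheep annotation, where fewer miRNAs were tested, and 26 without mouse virgin and mouse gestation day 17. Leaving out single arrays gave 35 to 53.

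Gestation against animals not pregnant had 1 call. There were 0 with quantile normalization, no scaling, normexp, the brightest probe, the authors' values, miRNAs detected on all 10 arrays, a floor 4 times lower, or without the 28 miRNAs at the floor. There were 2 with no filter, 2 with an intensity trend, 6 on slide 1 alone, 6 in sheep alone, 5 in mouse alone and 3 without mouse virgin and mouse gestation day 17. Leaving out single arrays gave 1 to 7.

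Lactation against gestation had 6 calls. There was 1 with quantile normalization, and there were 0 with the 75th percentile over all miRNAs, the brightest probe, the authors' values, no filter, slide as a term, slide 1 alone, mouse alone, or without mouse virgin and mouse gestation day 17. There were 22 without scaling, 13 among miRNAs detected on all 10 arrays, 24 with a floor 4 times lower and 15 without the 28 miRNAs at the floor, and 6, 5 and 3 of the 6 were shared with the 15, the 13 and the 22. For miR-103, lactation versus gestation turned to -0.0888 without scaling, where all miRNAs shifted by a median of -0.66, and for miR-361, lactation versus gestation turned to 0.0132 with normexp, where they shifted by 0.65, so neither turned relative to the other miRNAs. Leaving out single arrays gave 0 to 5.

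Lactation against animals not pregnant had 8 calls. There were 0 with quantile normalization, the brightest probe or the authors' values, 1 with the 75th percentile over all miRNAs, 14 with normexp, 2 with no filter, 29 with a floor 4 times lower, 1 with slide as a term, 4 on slide 1 alone and 3 without mouse virgin and mouse gestation day 17. Leaving out single arrays gave 1 to 8.

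The difference between species in the change from gestation to lactation had 2 calls. There were 9 with quantile normalization, 5 with the 75th percentile over all miRNAs, 1 without scaling, 0 with normexp, where miR-200b* turned to -0.23 and all miRNAs shifted by a median of -0.36, 4 with the brightest probe, 4 with the authors' values, 0 among miRNAs detected on all 10 arrays, 0 with a floor 4 times lower, 5 with slide as a term, 5 on slide 1 alone, 0 without the 28 miRNAs at the floor and 8 without mouse virgin and mouse gestation day 17. Leaving out single arrays gave 0 to 19, and without sheep lactation the model could not be fitted.

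Lists called by camera became 0 with an estimated correlation in each comparison that had any. With fry there were 5 between sheep and mouse, 1 between gestation and animals not pregnant, and 1 between lactation and gestation. That 1 was the milk-abundant list (adjusted p = 0.0172), which camera had not called, while the miR-200 family and fibroblast lists had an adjusted p of 0.185 and 0.111. Fry tests against no change, and camera against the other miRNAs. With quantile normalization there was 1 between sheep and mouse, 0 between lactation and gestation, and 1 for the difference between species. Between lactation and animals not pregnant, the milk-abundant list had an adjusted p of 0.0657 with quantile normalization, and striated muscle one of 0.0335.

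Counts of miRNAs that differed at least 2-fold moved as follows. From sheep cycle to gestation day 14 there were 30 with the 75th percentile over all miRNAs, 23 without scaling, 105 with normexp, 5 with the brightest probe, 40 with the authors' values and 6 among miRNAs detected on all 10 arrays. From day 14 to day 64 there were 32 without scaling, 7 with normexp and 7 among miRNAs detected on all 10 arrays. From day 125 to lactation there were 50 without scaling and 16 with normexp, and from cycle to lactation 100 without scaling. In mouse, from virgin to gestation day 10 there were 19 without scaling, 3 with normexp, 30 with the authors' values and 4 among miRNAs detected on all 10 arrays. From day 10 to day 17 there were 45 without scaling, 16 with normexp and 71 with the authors' values, and from day 17 to lactation day 2 there were 81 without scaling. From lactation day 2 to day 10 there were 32 without scaling, 4 with normexp and 33 with the authors' values, and from virgin to lactation day 10 there were 63 without scaling and 59 with the authors' values.

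The correlation between the species of the change into gestation was -0.215 without scaling, 0.247 with normexp and 0.124 with the authors' values. For lactation against animals not pregnant it was 0.305 without scaling and 0.328 with normexp. Agilent's total signal moved no count of calls by more than 1.5 times.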

Other observations

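The miR-29 family, which targets collagens, and the miR-17-92 clusters moved in opposite directions late in sheep gestation. List means of the miR-29 family on the 5 sheep arrays in stage order were -0.11, 0.37, 0.80, -1.60 and 0.25, and those of miR-17-92 were -1.90, -2.19, -2.42, -1.35 and -2.43. The directions into and out of day 125 were the same under each scaling, but rest on 1 array of that day, and no test was made.

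In mouse, miR-181a and miR-181b were higher late in the course than early. miR-181a stood at -5.11, -4.90, -3.24, -2.08 and -0.68 from virgin to lactation day 10, and miR-181b at -5.11, -5.11, -3.29, -1.77 and -0.87, with -5.11 the floor. In sheep, miR-494 stood at -3.79 in cycle, -0.80 and 0.64 at gestation days 14 and 64, and -3.46 at day 125. The control features hur_4 and hur_6 ran the other way over these arrays, with hur_4 at 8540, 5437, 1918 and 7051. In lactation hur_4 was 4014, yet miR-494 differed from cycle by 0.15 only. Whether the course of miR-494 reflects the arrays or the stage was not tested.

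The tests of the 3 patterns that follow were all chosen after the patterns were seen. Signal before scaling was lower in lactation than in gestation, with folds of 0.546 in sheep and 0.39 in mouse. A dimmer scan was argued against in sheep by the bright corner features, with a fold of 1.24 on slide 1, from 1 lactation array. The mouse fold of 1.16 crosses slides, as gestation day 10 was on slide 2, so it does not decide. On slide 1 the mouse features stood at 595 at gestation day 17, and at 622 and 561 at lactation days 2 and 10. The 75th percentile of signal was 937, 394 and 246 on these 3 arrays. Less RNA labelled or hybridised may explain the lower signal, and 5 of the 8 folds of the hur control features lay within 1.5 times of the miRNA fold, which leaves it open. A lower share of miRNA in the RNA of lactating gland was not tested and stays open too.

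Striated muscle miRNAs were high in virgin mice and at mouse gestation day 17. The slide as the whole cause was argued against, since virgin mice exceeded mouse gestation day 10 on the same slide by 3.78 in the list mean. Muscle tissue in the sample may be a source and stays open, since 4 of the 4 members were higher on both arrays than on the other mouse arrays, which restates the pattern and does not set muscle tissue apart from a difference of stage. miR-1, miR-133a, miR-133b and miR-206 stood at -0.73, -0.97, -0.50 and -3.11 in virgin mice and the first 3 stood at -1.66, -2.80 and -1.93 at day 17, where miR-206 lay just above the floor of -5.11. A difference of stage was not tested, with 1 array for each day.

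The miR-200 family was higher and fibroblast and smooth muscle miRNAs lower in lactation than in gestation, with a change in the gap of their list means of 2.70 and a standard error of 0.963, though in sheep the miR-200 mean was 0.40 in lactation against 0.75 at gestation day 125. Whether a larger share of epithelial cells lowered all other cell types alike was not decided. Endothelial miRNAs changed by 1.43 more than fibroblast ones, with a standard error of 0.357, past the 2 standard errors set for arguing against it. However, this rests on miR-126-3p alone, as the other of the 2 endothelial members lay at the floor on all arrays. The change of miR-126-3p itself was 0.67 in sheep and -0.26 in mouse. The fibroblast list did not move as one either. Its member miR-143 changed by -0.28 in sheep and -0.10 in mouse, and miR-199a-5p by -2.35 and -2.29. The comparison of the 2 lists therefore cannot argue against such a larger share. The gap kept most of its size with slide as a term, at 2.18 with a standard error of 1.04, but on slide 1 alone, at 2.20 with a standard error of 1.17, it lay within 2 standard errors of 0, so the slide stays open. The condition for excluding the slide was tightened after the first of these values had been seen, and the condition first written would have excluded it. A change in the fibroblasts themselves, or in their share, may underlie the pattern and was not tested.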
